A study of Mus musculus with 2 samples.

How the data were processed

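Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on MC3T3 sc4 cells, a mouse osteoblast line derived from calvaria. Per the labels, the antibody was directed against histone H4, and the design text of the series describes the assay as a map of acetylated histone H4. The 2 samples were 1 library from cells given the solvent DMSO and 1 library from cells given 20 µM SAHA (suberoylanilide hydroxamic acid, vorinostat), an inhibitor of histone deacetylases. Cells were grown in osteogenic medium and treated on day 4 for 2 hours, and the drug or its solvent stayed in place during a collagenase digest of 40 min. Chromatin was then crosslinked and sonicated to fragments of 200 to 500 bp, per the labels' protocols.

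The deposited data are 1 list of regions. Per the submitters' processing notes, CASAVA 1.7.0, BWA 0.5.9, SAMtools and MACS 1.4.0rc2 were used with genome build mm9. Per the file headers, MACS 1.4.0rc2 was run with the SAHA reads as the ChIP file and the DMSO reads as the control file, so the list holds regions with more tags in SAHA than in DMSO. A separate peak list of each library and a list of regions higher in DMSO were not analysed here. The file headers give an effective genome size of 1.87e+09 bp, a band width of 300 bp, a p cutoff of 1e-05, a tag size of 50 bp, a fragment size d of 141 bp and at most 3 duplicate tags kept per position. The smaller library was scaled to the larger, and local backgrounds were taken over 1 kb and 10 kb, per the file headers. After these steps 123676661 SAHA tags and 76214516 DMSO tags remained, so 1 DMSO tag weighed as much as 1.62 SAHA tags.

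The unit of each column was set as follows. The tag column holds whole counts of SAHA tags per region, as deposited. The score column, as deposited, holds 10 times the −log10 of a Poisson p-value, and a score of 50 is the cutoff. The fold enrichment column is a ratio of SAHA to the local DMSO background as the authors' caller computed it. The FDR column is a percentage as deposited. It was read by the definition known for this caller, which the file headers do not state: the number of regions called with SAHA and DMSO exchanged, at the same p or better, per 100 listed regions, held at 100. The list gives no DMSO value per region.

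From these columns the following were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The number of regions called with SAHA and DMSO exchanged was taken as the FDR times the number of listed regions at that score or above. Over the 23729 distinct scores with an FDR under 100%, this number fell with decreasing score in 0 cases beyond rounding of the FDR. The local DMSO level of each region was recovered as the Poisson mean for which the probability of more than the listed tags gives the listed score, at SAHA depth. This was done for the 61106 regions with a score under 3000, since higher scores run into the limit of the number format. In 75.8% of them the recovered level equalled, within the rounding of the score (0.005), a background that the caller could have used, against 1.67% by chance: the genome average, or a whole number of scaled DMSO tags in the region itself, in 1 kb or in 10 kb. For these, fold times level gave a whole summit height within 0.1 tags in 99.6% of the 41279 regions precise enough to test, against 20% by chance. Of the 11865 unmatched regions precise enough to test, 94.2% fitted both conditions when the tags used by the caller were taken to be 1 fewer or up to 15 more than listed, against 3.38% for the same number of other shifts. The level of all 14796 unmatched regions is therefore approximate, and in 15.1% of them it came out below the genome average by over 0.1%, which the caller's method does not allow.

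A model based on summit heights in place of tags was tried first and left out, since its heights came out whole in 20.2% of 38799 regions, near the 20% expected by chance. The caller is known to use the highest of its backgrounds, which the file headers do not state. In a matched region the recovered level is thus an upper limit of the scaled DMSO tags and the ratio of SAHA tags to it a lower limit, except where the level is the DMSO count of the region itself and both are exact. In an unmatched region they are approximate and no limits. For named regions at the score ceiling of 3100, the level that would give a score of 3000 was taken as the highest the caller could have used. This takes the listed tags as those tested, and 15 more tags would lower the ratio limits of the 6 such regions among the 10 by at most 1.52%. On simulated lists, 99.7% of 18121 regions were given the right kind of background, with 1 kb and 10 kb counted as the same kind. The level was off by at most 0.00343%, and the number of exchanged regions by at most 2.97 of 40000. The simulated scores were made from exactly the listed tags, so this accuracy does not carry over to the unmatched regions.

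With 1 library per condition there was no replicate check, and no p-value between conditions was computed. Intervals are 95% intervals (Wilson for shares, exact Poisson for tags and numbers of regions, exact binomial for a ratio of 2 counts, order statistics for medians). Those for tags, shares of tags and ratios of single regions cover counting error at most, since tags without molecular identifiers are not independent molecules. Those for shares, numbers and medians over regions treat regions as independent. Regions lay in clusters, so these intervals may be too narrow. For a ratio to a recovered level, the interval covers the SAHA tags alone, with the level taken as known. Where the level is the region's own DMSO count, the exact binomial interval covers both counts. Before the data were examined, it was fixed which genes would be named. These were a fixed set, members of the gene lists, and the genes of the 10 regions with the highest fold enrichment in each condition. Since regions were not assigned to genes, only the positions of the 10 regions of highest fold in this list are given from that plan. Other named regions were chosen after their values were seen and are marked so. The overlap of peak sets, the change over shared regions, the position relative to genes and gene lists were planned for tables that would allow them. None was made, because the list holds 1 direction only and the gene table used here is on the assembly GRCm38. Its coordinates differ from those of mm9 and were not converted. Regions are therefore given by position, without gene names. The density per chromosome was taken over the span from the first to the last region on it. Alternatives were a score of at least 100, a fold of at least 10 and an FDR of at most 1%, all planned, and those added after the data were seen, such as autosomes only, joined regions and other scalings.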

Results

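The data were 1 ChIP-seq library of histone H4 from MC3T3 sc4 osteoblasts treated with SAHA and 1 from cells treated with DMSO. The SAHA library held 126938706 tags, of which 97.4% were kept after the authors' limit on duplicates. The DMSO library held 116209155 tags, of which 65.6% were kept. The file headers give a redundant rate of 0.03 for SAHA and 0.34 for DMSO. The design asks where in the genome 2 hours of histone deacetylase inhibition changed histone H4 acetylation in differentiating osteoblasts. Neither condition had a replicate, so each difference below compares these 2 libraries only, and its spread between cultures is unknown.

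In the SAHA library, 61400 regions on 21 chromosomes held more histone H4 tags than the DMSO background. Most were short and moderate. The median region was 1337 bp long (quartiles 860 and 2443 bp) and held 215 SAHA tags (quartiles 122 and 471). The regions covered 128.3 Mb, or 6.86% of the effective genome, and held 22.1% of the kept SAHA tags (the 95% Wilson interval is narrower than the rounding). The median fold enrichment at the summit was 3.93 (quartiles 3.37 and 4.72), where fold, score and FDR are the authors' values throughout. In 81.0% of regions the fold was under 5, and in 148 regions it was 10 or more. These 148 were longer, with a median of 6454 bp. At a score of at least 100 the list held 38356 regions. Broad regions were a minority, with 4821 longer than 5 kb and 821 longer than 10 kb. The p-values behind these calls come from a Poisson model of 2 libraries, and the deposited FDR ran from 58.23% to 100%.

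The FDR column also carries the opposite comparison. Read by the caller's own definition, which the file header does not spell out, it implied 40653 regions with more tags in DMSO than in SAHA at the cutoff used for the list, or 66.2 per 100 listed regions. At scores of at least 100 and 150 the implied numbers were 26393 and 16144. The balance between the directions changed with the score. Equal scores need not mean equal evidence in the 2 directions, because the DMSO library was the smaller (scaling factor 1.62). The list does not show how tags were weighed in the exchanged comparison. At scores of 50 to 90 there were 57.1 implied DMSO-high regions per 100 SAHA-high ones. At scores of 90 to 120 the directions were about equal, with 8566 DMSO-high against 8263 SAHA-high regions. From 150 to 550 the SAHA-high regions prevailed, with 20311 against 8954, or 44.1 DMSO-high per 100. At scores of 557.07 and above the FDR stood at 100%, so at least 7127 DMSO-high regions were matched against the 7127 SAHA-high ones. These strongest calls made up 11.6% of the SAHA-high regions and at least 17.5% of the implied DMSO-high regions. The lowest FDR, 58.23%, was reached at a score of 166.82. The implied numbers carry a rounding error of up to 3.07 regions and, like the list, no replicate error. The positions of the DMSO-high regions were not analysed here.

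**Figure D1:**
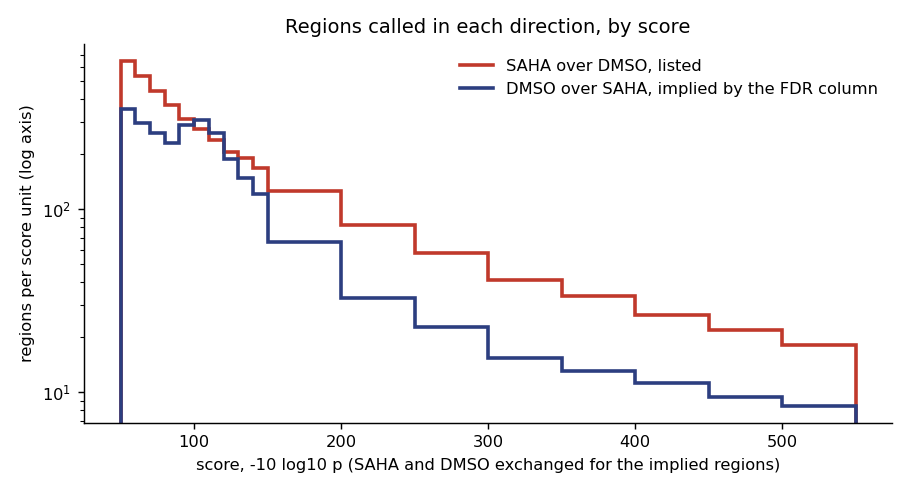
Number of regions per score unit (log axis) against the score, 10 times the −log10 of the p-value, for the listed SAHA-over-DMSO regions and for the DMSO-over-SAHA regions implied by the FDR column. The lines meet at scores of 90 to 120, with 8566 DMSO-high and 8263 SAHA-high regions, and part above 150; scores above 550 are left out because the FDR is held at 100% there.

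Most SAHA-high regions lay where the DMSO level was less than 1.5 times the genome average. The local DMSO level was recovered for 61106 regions and is given as a multiple of the genome average, which is 66.1 tags per kb at SAHA depth. Its median was 1.29 times the average (quartiles 1.02 and 1.72). It was under 1.5 times the average in 65.0% of regions (95% Wilson interval 64.6 to 65.4%) and under 2 times in 83.9%. In 13336 regions (21.8%) it did not exceed the average by more than 0.1%, and in the other 78.2% it did. The same tolerance holds wherever a level is given as at or below the average. A level of 3 to 5 times the average was found in 2272 regions (3.72%), and 140 regions had more. The recovered level is an upper limit of the DMSO signal where it matched a background and approximate in the other 14796 regions. Stretches without a SAHA-high region were not analysed here. At equal SAHA tags, a region of lower DMSO level passes the cutoff more easily, so these shares cannot show a preference for such levels.

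The SAHA tags of each whole region were also set against the local DMSO level. The summit fold sets the highest SAHA point against that same level, so the whole-region ratio is lower by construction. The DMSO height at the summit is not in the list, so the fold is no SAHA to DMSO change at that point. The median ratio of SAHA tags to that level was 1.80 (quartiles 1.59 and 2.04). It was at least 2 in 17107 regions (28.0%), at least 3 in 638 regions (1.04%) and under 1.2 in 938 regions (1.54%). In the 8361 regions whose level was their own DMSO count, the median counts were 253 SAHA tags and 86 DMSO tags, or 139.6 after scaling, and the median ratio was 1.77. Without depth scaling the median ratio over all 61106 regions was 2.92, and in the 79 regions with a fold of at least 10 and a recovered level it was 3.08 with scaling.

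Regions with a higher recovered DMSO level were longer and had a lower ratio to that level. Regions at or below the average had a median length of 821 bp and a median ratio of 1.98 (quartiles 1.84 and 2.22). Regions at 2 to 3 times the average had a median length of 3299 bp and a median ratio of 1.46 (quartiles 1.34 and 1.63). Above 5 times the average the median length was 9754.5 bp and the median ratio 1.16 (quartiles 1.11 and 1.23). The median summit fold changed little over the same range, from 4.18 to 3.62 and 3.86. A longer region with more tags passes the score cutoff at a smaller ratio, and the ratio is taken over the same level that sorts the regions, itself often an upper limit, so part of this trend is built in.

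**Figure D2:**
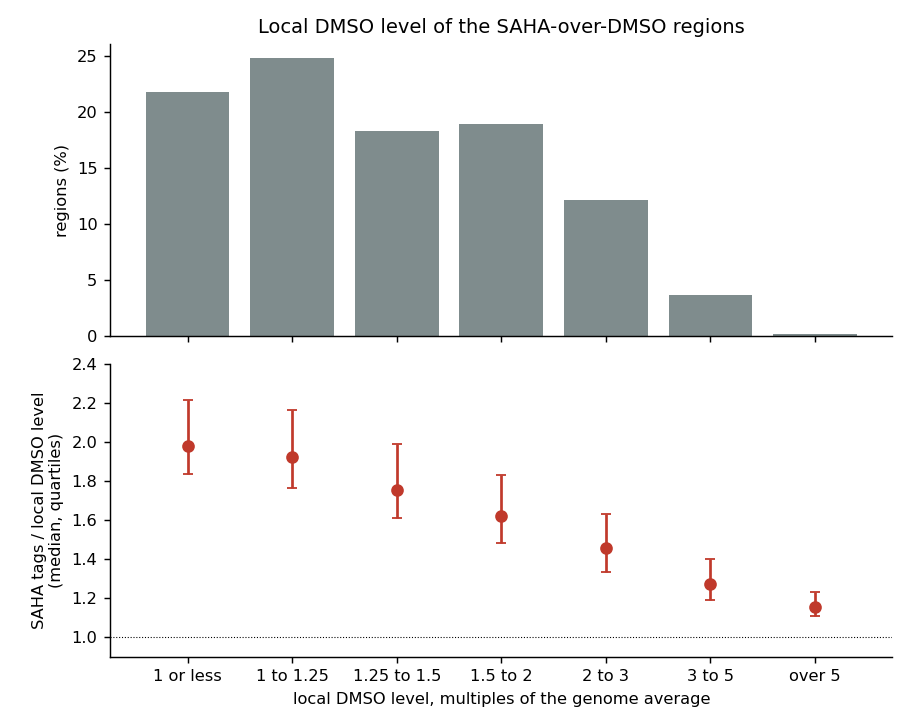
Upper plot, percentage of SAHA-over-DMSO regions by their local DMSO level in multiples of the genome average; lower plot, median SAHA tags over that level, with bars from the lower to the upper quartile over regions. The median ratio is 1.98 in regions at or below the average and 1.16 in those above 5 times the average.

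In 16514 regions (27.0%) the level matched DMSO tags within 1 kb and in 10378 (17.0%) those within 10 kb. In these, DMSO tags were denser in the window used than over the region as a whole. A level that fitted both windows was counted under 1 kb, and the simulation did not test this split. The genome average set the level in 11057 regions (18.1%) and the region's own DMSO tags in 8361 (13.7%). The other 14796 regions (24.2%) could not be assigned to a background.

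The 10 regions of highest summit fold lay on 9 chromosomes and had folds of 14.15 to 17.48. All 10 had an FDR of 100%, with scores of 1077.02 to 3100. At their scores, at least as many regions were thus implied with SAHA and DMSO exchanged. Positions are in build mm9, and genes at these positions were not looked up. The highest fold, 17.48, was at chromosome 13, 94734018 to 94748318, a region of 14.3 kb with 3933 SAHA tags (95% Poisson interval 3811 to 4058), or 4.16 times the genome average density. Its DMSO level was at most 2.16 times the average, and its ratio at least 1.92, taking the listed tags as those tested. The next was at chromosome 9, 43750006 to 43754946, with a fold of 15.94 and 1599 SAHA tags, at least 2.99 times the DMSO level. At chromosome 4, 101387669 to 101391028, the fold was 15.55 and the DMSO level did not exceed the genome average. This region held 951 SAHA tags, at least 4.28 times the DMSO level (95% Poisson interval 4.01 to 4.56). At chromosome 2, 155600144 to 155602298, 740 SAHA tags stood against a DMSO level of at most 160.9, a ratio of at least 4.60. Its interval, 4.27 to 4.94, leaves out the counting error of the DMSO tags behind that level. The shortest of the 10, 877 bp at chromosome 16, 86280637 to 86281513, held 295 SAHA tags, at least 5.09 times a DMSO level that did not exceed the genome average (interval 4.52 to 5.70). No other of the 61106 regions had a higher recovered ratio. The remaining 5 were at chromosome 1, 137638904 to 137649863 (fold 15.26, ratio at least 1.89), chromosome 5, 139348922 to 139368380 (fold 14.91, ratio at least 1.65) and 115278103 to 115281133 (fold 14.15, ratio about 3.38), chromosome 8, 73218455 to 73242988 (fold 14.84, ratio at least 1.49), and chromosome 10, 76955570 to 76973966 (fold 14.68, ratio at least 1.63). The level behind the ratio of about 3.38 matched no background. It was 0.987 times the genome average, lower than the caller's method allows. With the listed tags over the genome average itself, that ratio would be 3.33.

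The longest region, chosen after its values were seen, spanned 36.1 kb at chromosome 1, 92525245 to 92561349, with a summit fold of 11.87 and 15569 SAHA tags. Its DMSO level was 6.01 times the genome average, and the SAHA tags over the whole region were 1.09 times that level (interval 1.07 to 1.10, from the SAHA tags alone). This level matched no background and need not be the DMSO count of the region, so the ratio is approximate. Among regions with a DMSO count of their own, also chosen after their values were seen, the highest ratio was at chromosome 10, 23129466 to 23131116. There 509 SAHA tags stood against 69 DMSO tags, a scaled ratio of 4.55 (95% exact binomial interval 3.53 to 5.93). Its FDR was 100%.

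SAHA-high regions were clustered along the chromosomes. Of the 61379 gaps between neighbouring regions, 67.9% were 10 kb or shorter, against 26.6% on average and 26.8% at most in 20 random placements over the same chromosome spans. At 1 kb or shorter the shares were 36.3% and 7.54%. Placements over whole spans do not allow for stretches where few tags can map, and 1 broad domain may be listed as several adjacent regions. No DMSO-high or single-library list was compared, so the clustering cannot be tied to SAHA. Joining regions across gaps of up to 10 kb gave 19740 clusters, of which 8694 held a single region. The 1061 clusters of 10 or more regions together held 17024 regions. Joining across gaps of up to 1 kb alone reduced the 61400 regions to 39128.

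The cluster with the most regions lay at chromosome 5, 5084663 to 5369300, where 81 regions covered 49.5% of 284.6 kb. Its covered part held 201.5 SAHA tags per kb, 3.05 times the genome average, and the median ratio to the local DMSO level was 1.82 (range 1.15 to 2.70). The next, at chromosome 7, 89491921 to 89774247, held 80 regions over 282.3 kb with 65.1% covered and a median ratio of 2.03. Clusters of 65, 56 and 55 regions followed at chromosome 4, 97453054 to 97679569, chromosome 13, 15560928 to 15736554, and chromosome 14, 21678979 to 21865708. The median DMSO level in these 5 clusters was between 1.15 and 1.45 times the genome average. The clusters were chosen after the data were seen.

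**Figure D3:**
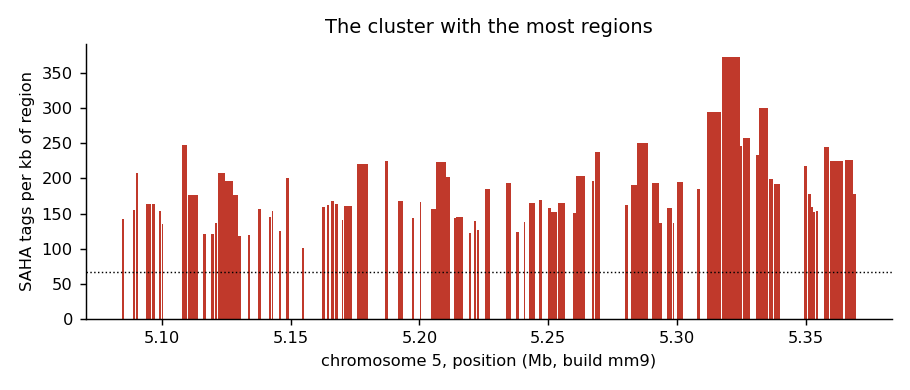
SAHA tags per kb in each of the 81 regions of the cluster at chromosome 5, 5084663 to 5369300 (build mm9); each bar spans its region and the dotted line is the genome average of 66.1 tags per kb. All regions stand above the average, as the calling cutoff requires, and they cover 49.5% of the stretch.

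The autosomes carried 25.6 regions per Mb and the X chromosome 3.60 (574 regions, 95% Poisson interval 3.31 to 3.91), or 14.1% of the autosomal density (interval 13.0 to 15.3%). It was 7.91% among regions with a DMSO level above the genome average and 0% among the 148 regions with a fold of at least 10. Of all 61400 regions 574 lay on X, so few or none of the 148 would be expected there. The 0% thus shows no stronger deficit. Among the 19 autosomes the density ran from 19.8 regions per Mb on chromosome 6 to 32.9 on chromosome 18. The X regions were shorter, with a median of 908.5 bp against 1337 bp on the autosomes among regions with a recovered level. They held 134 SAHA tags per kb (median) against 160.2. Their DMSO level was at or below the genome average in 56.1% of cases against 21.5% on the autosomes. The median ratio of SAHA to the local DMSO level was 1.88 on X, above the 1.67 to 1.85 of the single autosomes. At a level no higher than the average it was 1.93 on X and 1.98 on the autosomes, and above that 1.76 and 1.73. The cutoff and the genome-average floor shape these ratios. The Y chromosome held 2 regions.

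**Figure D4:**
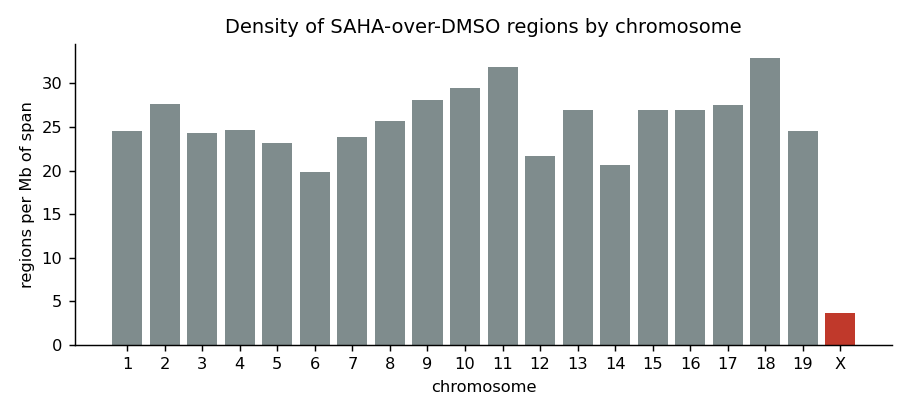
SAHA-over-DMSO regions per Mb on each chromosome, over the span from its first to its last region; chromosome Y, with 2 regions, is left out. Chromosome X has 3.60 regions per Mb, and the autosomes have between 19.8 and 32.9.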

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

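The planned FDR limit of 1% left 0 regions, so no other value could be given under it. The number of SAHA-high regions was 38356 at a score of at least 100 and 148 at a fold of at least 10. Apart from the median length and fold under these 2 limits, the other alternatives here were added after the data were seen. Joining regions within 1 kb left 39128, and autosomes alone held 60824. The implied DMSO-high regions numbered 26393 at a score of at least 100 and 16144 at 150. The median ratio of SAHA tags to the local DMSO level was 1.93 at a score of at least 100, 3.08 at a fold of at least 10 (79 regions, as 69 others of that fold had no recovered level), 1.82 in regions matched to a background, 1.77 in those with a DMSO count of their own, 1.75 with a pseudocount of 5 and 2.92 with no depth scaling. The share of regions with a DMSO level under 1.5 times the average was 59.7% at a score of at least 100, 64.6% in the same 79 regions and 67.2% in matched regions. The X density was 10.5% of the autosomal one at a score of at least 100, 16.9% with joined regions and 7.91% among regions above the genome average. It was 0% among the 148 regions with a fold of at least 10, which are too few to show a change. Some of these shifts follow by construction. Stricter limits and joining leave fewer regions, and a pseudocount lowers ratios above 1. Without depth scaling, each ratio is larger by the scaling factor of 1.62. A shorter gap limit must give a lower share of gaps between regions. The share of 64.6% in the 79 regions was close to the 65.0% of all 61106 regions. The cause of the other shifts was not tested. Among the further alternatives, for the DMSO-high regions per 100, the gaps, the median length and the median fold, 10 moved the value beyond its interval, most for the median length, 6454 bp at a fold of at least 10, and 2, the length and fold on autosomes alone, did not. Other thresholds planned for the overlap of peak sets, the change over shared regions, the position relative to genes and gene lists were not run, since those results were not made. No alternative can stand in for replicates, and the unequal loss of duplicates (2.57% of SAHA tags and 34.4% of DMSO tags) cannot be undone from the list.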

Other observations

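All tests in this part were chosen after the results were seen.

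The regions of chromosomes 19, 6 and 17 had the highest SAHA density among the autosomes, with medians of 180.4, 174.3 and 171.0 tags per kb, against a median of 160.2 over the 19 autosomes. Their median DMSO level was 1.60, 1.57 and 1.46 times the genome average, and their ratio of SAHA to that level was the lowest, at 1.67, 1.67 and 1.72. A region of 729 bp on X, chosen after its value was seen, at 109484219 to 109484947, had a DMSO level 22.4 times the genome average, with 667 DMSO and 1265 SAHA tags. Its scaled ratio was 1.17 (95% exact binomial interval 1.06 to 1.29).

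DMSO-high regions were as many as SAHA-high ones at scores of 90 to 120 (103.7 per 100) and at least as many at 557.07 and above, and fewer between 150 and 550. A candidate explanation is the low complexity of the DMSO library, whose redundant rate was 34% against 3% for SAHA. It cannot be told apart from the treatment, because each condition has 1 library. The DMSO tags were scaled to the SAHA library by the tags kept after filtering, so a rise of acetylation over the whole genome would not show as such. An error of the scaling factor was also considered and not tested, as the list holds no value that could exclude it.

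The X chromosome held 14.1% of the autosomal density of SAHA-high regions. A single copy of X may account for part of this, since fewer tags would fall below the caller's genome-average floor. Halving the tags and the DMSO level of each autosomal region, with that floor kept, left 28.5% of them past the cutoff. The observed X density lies below that value, so this halving alone did not reach the X deficit. The copy number of X in these cells was not measured, so whether it accounts for part of the deficit stays open. Among regions above that floor the X density was 7.91% of the autosomal one, but the floor and the copy number of X cannot be separated in this list, and no biological explanation was tested.

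Chromosome 6 combined the lowest density of regions among the autosomes, 19.8 per Mb against 20.7 for the next, with a high tag density inside them. The low density runs against densely packed regions as the reason, but packed signal can merge into fewer calls. The median region on chromosome 6 was long, at 1678 bp, though that on chromosome 19 was longer, at 1786 bp. Regions covered 5.03% of the span of chromosome 6, within the range of the other autosomes (3.74% on chromosome 14 to 7.03% on chromosome 11). Extra copies of chromosome 6 in the cell line may contribute and predict a raised lower end of the tag density as well; its 10th percentile was 129.9 SAHA tags per kb on chromosome 6, against a median of 122.9 and a maximum of 129.4 (chromosome 19) over the other autosomes. The limits for both comparisons were set after the results were seen, so neither outcome is a test. Under the first limits, without a margin, the percentile had favoured extra copies and the density had gone against packing. A later margin of 1 SD over the other autosomes, also set after the values were known, left both undecided. The lead over chromosome 19 is small and the calling cutoff moves with the local background, so these explanations cannot be told apart, and no biological one was tested.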
